A study of Gallus gallus with 2 samples.

How the data were processed

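RNA of chicken intestinal intraepithelial lymphocytes was compared on 2 two-colour Agilent arrays of a chicken 44K design. Per the labels, the birds were broilers of day 14, and each array carried RNA of curcumin-fed birds in one dye and RNA of non-treated control birds in the other. Curcumin was in Cy5 on array 1 and in Cy3 on array 2. The labels call array 2 the second biological replicate and also the dye exchange of the first. It therefore stays open whether both arrays hold the same RNA. In that case the p-values of single genes measure technical spread only. The series title names Eimeria infection, but no label of these samples states an infection. Both arrays lay on 1 slide, so slide and scan did not differ between them.

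Per the file headers, the spot and local background intensity values were deposited as Agilent Feature Extraction 10.7.3.1 measured them, without background correction, and the processed intensity values were background-subtracted, detrended and dye-normalized by that software. Per the file headers, the deposited log ratio is the log10 of Cy5 over Cy3 processed intensity. The authors' series value table held the same log10 ratios, turned to curcumin over control. The largest difference from the turned scanner log ratio was 5e-10 on array 1 and 4.96e-06 on array 2, and the median value was 0 on both arrays, so scale and direction were settled by the comparison.

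The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Mean spot and median local background intensities were corrected with limma's normexp (offset 50), fitted on all spots, and log2 ratios were normalized by loess within each array with control spots at weight 0. Probes that the scanner software marked as feature outliers on either array were left out. Probes were tested when well above background in the curcumin channel of both arrays or in the control channel of both, which kept 17766 of 42034 probes. After turning array 2, the ratios were fitted with lmFit and eBayes, with 1 residual degree of freedom per probe and a gene-specific dye effect left in the residual. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all probes tested. A sign test on 2 arrays could not have reached 0.05. No gene had a saturated spot.

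The normexp fit of array 1 differed from that of array 2. On that array 9 spots had a local background above 1000, up to 47200 in Cy3, and on array 2 there were 0. The fitted Cy3 background mean was -338 with an SD of 550 on array 1, against 3.68 and 1.89 on array 2. Without spots marked as feature or background outliers the array 1 values were 3.58 and 0.783. The setting with all spots was the one fixed beforehand and is the one reported. The fit without outlier-marked spots, and that without the spots of bright local background, were chosen after seeing the data, when the numbers of changed genes under several settings were already known, and their values are given beside the leading counts. The procedure was tested on simulated data built on the spot brightness of array 2 and on real local backgrounds, with 200 changed probes. With the local backgrounds of array 2 on both arrays and 17766 probes run, 66% of 100 probes changed 4-fold were called and 5% of 100 changed 2-fold. A second run subtracted the local background of array 1 from simulated array 1 spots whose intensities still held that of array 2. There 0% of either were called, and those changed 4-fold had a median log2 ratio of 0.80 in size against a true 2. Such spots do not copy the real array 1, so this run does not measure what its fit misses. With outlier-marked spots left out of the fit of that second run, 16296 probes were run. Then 69.2% of the 91 remaining probes changed 4-fold were called and 6.45% of the 93 changed 2-fold.

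Genes were named through RefSeq accessions, gene IDs, symbols or synonyms of the GRCg7b gene table, used for names only. Accessions named 5233 probes, gene IDs 3649, symbols 884 and synonyms 93. Genes whose symbol came from the RefSeq table alone, such as CSRNP1, LPGAT1, CTRC and PDCL3, were counted as named although the rule for named genes spoke of symbols in the files, a choice made after the data were seen. A further 121 probes kept the name in the files, and 32054 had no symbol. Coordinates are those of the probes on galGal2, as the files give them. A gene with several probes was represented by the brightest, which left 5710 named genes. Fold thresholds were 2 on each array. For probes not well above background in a condition on both arrays, a fold is given only as a bound, from channel values after loess and Aquantile normalization.

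Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for named genes were fixed. How list members were matched to the array was settled after a first look at the genes with the largest ratios. The rule took, per direction, the 12 genes with the largest mean log2 ratio among those past an adjusted p of 0.05, with open places filled from genes at least 2-fold apart on both arrays as values only. It also took 4 members of each list past the test, in the direction of the list, and 2 members of each other list with the same direction on both arrays, by size of the mean log2 ratio. Some genes that the rule took are not reported here and were not replaced. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera sets the members of a list against the other genes. Its p takes genes, not birds or arrays, as the units. This left 28 lists, and 3 had fewer genes: cytotoxic and NK cell genes, heterophil granule and marker genes, and stroma and smooth muscle markers. The alternatives were other background corrections, normalizations, filters, eBayes settings, probe summaries and list tests, the series value table, and each array alone. Further alternatives, added after seeing the data, left out spots marked as outliers, spots of bright local background, probes with a background outlier mark, and 10 list matches that a reader could doubt. The number of arrays limits the precision of every value.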

Results

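Intraepithelial lymphocytes are T cell-rich cells of the intestinal lining. Their RNA from broilers of day 14 given turmeric's pigment curcumin was compared with that of non-treated controls on 2 arrays with exchanged dyes. The question was which transcripts differ with the diet. Of 42034 probes, 22701 were well above background in the curcumin channel and 15753 in the control channel of array 1, and 17884 and 22289 on array 2. The Cy5 channel held the larger number on both arrays. The precision is limited by the 2 arrays, which may hold the same RNA.

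The lowest mean log2 ratios among named genes at least 2-fold lower on both arrays were those of pancreatic digestive enzymes. PNLIPRP1, a pancreatic lipase-related protein named PNLIP on the array (chromosome 6, 27910792 to 27910851), had a mean log2 ratio of curcumin over control of -2.73 ± 0.040 (SD, n = 2), or 6.62-fold lower. AMY2A, a pancreatic amylase named AMY1C on the array (chromosome 8, 24652 to 24711), stood at -2.65 ± 0.13, or 6.30-fold lower. The elastase CELA2A had a mean of -2.10 ± 0.44, the carboxyl ester lipase CEL -1.86 ± 0.98, the chymotrypsin CTRC -1.67 ± 0.80 and the carboxypeptidase CPB1 -1.51 ± 0.53. Genes outside the enzyme list at least 2-fold lower on both arrays were SHH, a signalling protein (-1.47 ± 0.36), PDCL3 (-1.23 ± 0.16) and the glutathione transferase GSTT1 (-1.22 ± 0.14). With median centring in place of loess these stood at -0.65, -0.50 and -0.39.

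Among genes at least 2-fold higher on both arrays, CSRNP1, a nuclear protein of the immediate early response (chromosome 2, 4719622 to 4719681), had a mean log2 ratio of 2.24 ± 1.43 (SD, n = 2), or 4.74-fold higher, with 3.26 on array 1 and 1.23 on array 2. GDF2, a BMP-family ligand, stood at 2.04 ± 1.08, the kinase MAP3K2 at 1.80 ± 1.02, and FZD4, a Wnt receptor, at 1.71 ± 0.60. HCRT, which encodes the neuropeptide orexin, had a mean of 1.71 ± 0.63, the glutamine synthetase GLUL 1.65 ± 0.79, UGT8 1.64 ± 0.89 and YF, a major histocompatibility class I gene, 1.61 ± 0.76. LPGAT1 followed with 1.56 ± 0.37, the haemoglobin gene HBA1 with 1.55 ± 0.11, SYNGR1 with 1.48 ± 0.59 and BRD1 with 1.48 ± 0.14. The other probes of BRD1 had mean log2 ratios of 0.09 and 0.06. Without the bright-background spots in the normexp fit HBA1 stood at 2.43. With processed signals HBA1 stood at 3.09, GDF2 at 3.88, HCRT at 2.67 and YF at 2.71. Of the enzyme genes, CEL stood at -3.12, CTRC at -2.98 and CPB1 at -2.40 there. The other genes given so far moved by less than 1.5 times with processed signals.

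In all, 40 named genes were at least 2-fold higher and 10 at least 2-fold lower on both arrays, a description without a test. Other processing gave 243 higher and 200 lower with processed signals or the series value table, 6 and 0 with median centring, and 0 and 0 with scaling between arrays. No gene passed limma's test across probes. Of 5710 genes and 17766 probes, 0 had an adjusted p under 0.05. The lowest adjusted p was 0.163, while 772 genes and 2103 probes had an unadjusted p under 0.05. By chance 888 probes would be expected there. All the values in the 2 preceding paragraphs are therefore values only. In simulated data with the local backgrounds of array 2 on both arrays, 5% of 2-fold and 66% of 4-fold changes were called. A count of 0 therefore does not show that no gene changed. No simulation copied the real array 1. Without the 9 spots of array 1 with a bright local background in the normexp fit, 15 genes passed, 6 higher and 9 lower, 74 genes were at least 2-fold higher and 22 lower. Without outlier-marked spots in the fit and in the test, which left 5218 of 5710 genes, 9 genes passed, 83 genes were at least 2-fold higher and 21 lower. Both settings were chosen after seeing the data. The 9 genes were PNLIPRP1, AMY2A, CEL, CTRC and CPB1, all lower, and GDF2, HCRT, YF and PMM2, all higher. PMM2, which the rule for named genes does not hold and which was chosen after its values were seen, had a log2 ratio of 2.77 there. A planned fit with an intensity trend and robust eBayes called 125 genes, 103 higher and 22 lower, of which 6 were among those 9.

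**Figure D1:**
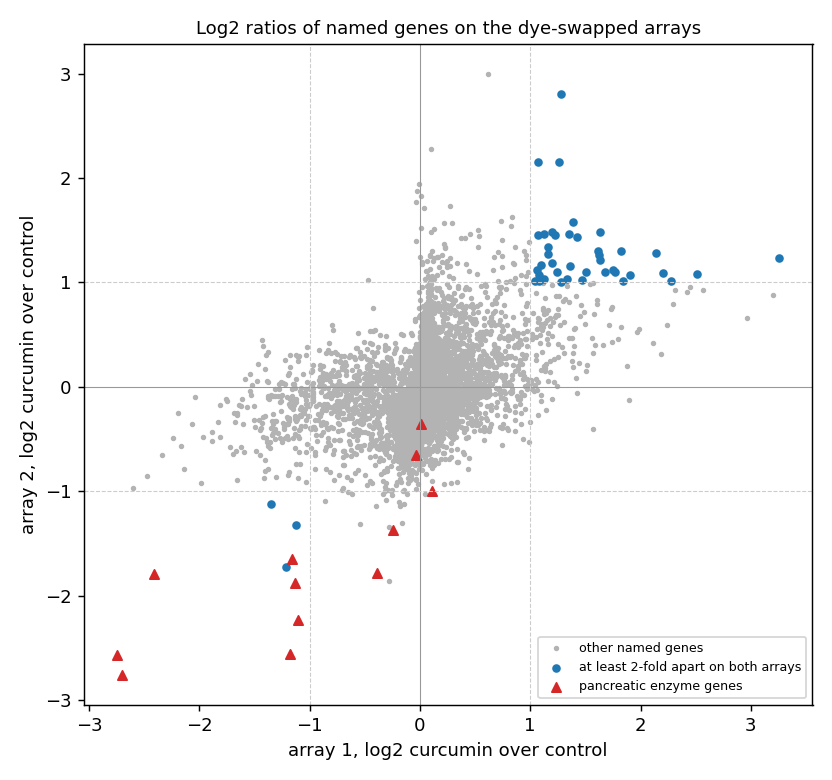
Log2 ratio of curcumin over control of each named gene on array 1 (horizontal axis) and array 2 (vertical axis), with dashed lines at 2-fold. Each point is a gene, blue points are at least 2-fold apart on both arrays, and red triangles are the 12 pancreatic enzyme genes, of which 10 lie below 0 on both arrays.

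Of the 28 gene lists, 4 passed camera, all lower with curcumin, though the NRF2, ribosomal and reference lists had higher medians with median centring in place of loess. Pancreatic enzyme genes fell as a list. Of 12 measured members, 10 were lower on both arrays and 2 had opposite directions. The median log2 ratio was -1.46, with an adjusted p of 3.63e-13 in camera. That p takes genes as its units and does not measure the spread between birds or RNAs. With an estimated correlation the list did not pass (adjusted p = 0.892), nor in fry (adjusted p = 0.417). Adjusted over the list alone, 8 members passed, all lower, against 0 over all genes. The list passed in all 13 alternative settings of normalization, filter and matching, with medians from -2.42 to -1.04 and adjusted p from 3.16e-25 to 0.00197. Of these settings, processed signals and the series value table held the same ratios. With an estimated correlation no list passed, but that test rests on 1 residual degree of freedom and could hardly have reached 0.05 after adjustment. The NRF2 list had an estimated correlation of 0.0069, under the preset 0.01, and still moved from an adjusted p of 0.00884 to 0.892. The test with an estimated correlation therefore cannot decide whether a list shifted. The estimates for the pancreatic (0.394), ribosomal (0.282) and reference (0.127) lists lay above the preset 0.01. They rest on 1 residual degree of freedom too. Where the genes of a list correlate more than the preset, its camera p comes out too small.

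NRF2 targets and antioxidant enzymes, which detoxify reactive compounds, fell as a list with a median log2 ratio of -0.32 and an adjusted p of 0.00884, and an adjusted p = 0.892 with an estimated correlation. Of 30 members, 17 were lower and 4 higher on both arrays. Adjusted over the list alone, 1 passed, against 0 over all genes. Besides GSTT1, the peroxiredoxin PRDX1 had a mean log2 ratio of -0.88 ± 0.97 (SD, n = 2), the metallothionein MT4 -0.85 ± 0.20 and GSTK1 -0.79 ± 0.49. Ribosomal proteins passed with an adjusted p of 0.0130 and a median of -0.35, and had an adjusted p = 0.892 with an estimated correlation. They lay inside the central 95% of random lists matched in brightness, at percentile 10.74. Ribosomal proteins were thus not set apart from other genes as bright. Of 27 members, 16 were lower and 6 higher on both arrays, with RPL5 at -1.79 ± 1.15, RPL4 at -1.20 ± 0.96 and RPS23 at -1.15 ± 0.38. Reference genes passed with an adjusted p of 0.0358 and a median of -0.59, and had an adjusted p = 0.892 with an estimated correlation. Of 11 members, 8 were lower and 3 higher on both arrays, with the elongation factor EEF1A1 at -1.66 ± 1.14 and PGK2, named PGK1 on the array, at -1.10 ± 0.74. RPL4 counts in this list too. Adjusted over the list alone, 0 ribosomal protein genes passed, and 2 reference genes passed higher and 5 lower. Without outlier-marked spots in the normexp fit and the test, these 3 lists did not pass (adjusted p of 0.386, 0.727 and 0.386), with medians of -0.21, 0.011 and -0.51. Leaving background-outlier probes out of the test alone, with normexp on all spots, also ended the ribosomal and reference calls but not the NRF2 call. Without the bright-background spots and with 5710 genes tested, the 3 lists did not pass either (adjusted p of 0.296, 0.916 and 0.123), with medians of -0.22, -0.070 and -0.52. Without outlier-marked spots PRDX1 stood at -0.43, MT4 at -0.32 and RPS23 at -0.49. Over the 13 alternatives their adjusted p ranged from 0.00397 to 0.625, from 0.0025 to 0.954 and from 0.00279 to 0.856. With median centring their medians were 0.48, 0.75 and 0.38, and ribosomal proteins passed as higher there (adjusted p = 0.0237). The lower pancreatic enzyme values, and HBA1 and HBBA at least 2-fold higher, stood on the same arrays as all these groups.

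**Figure D2:**
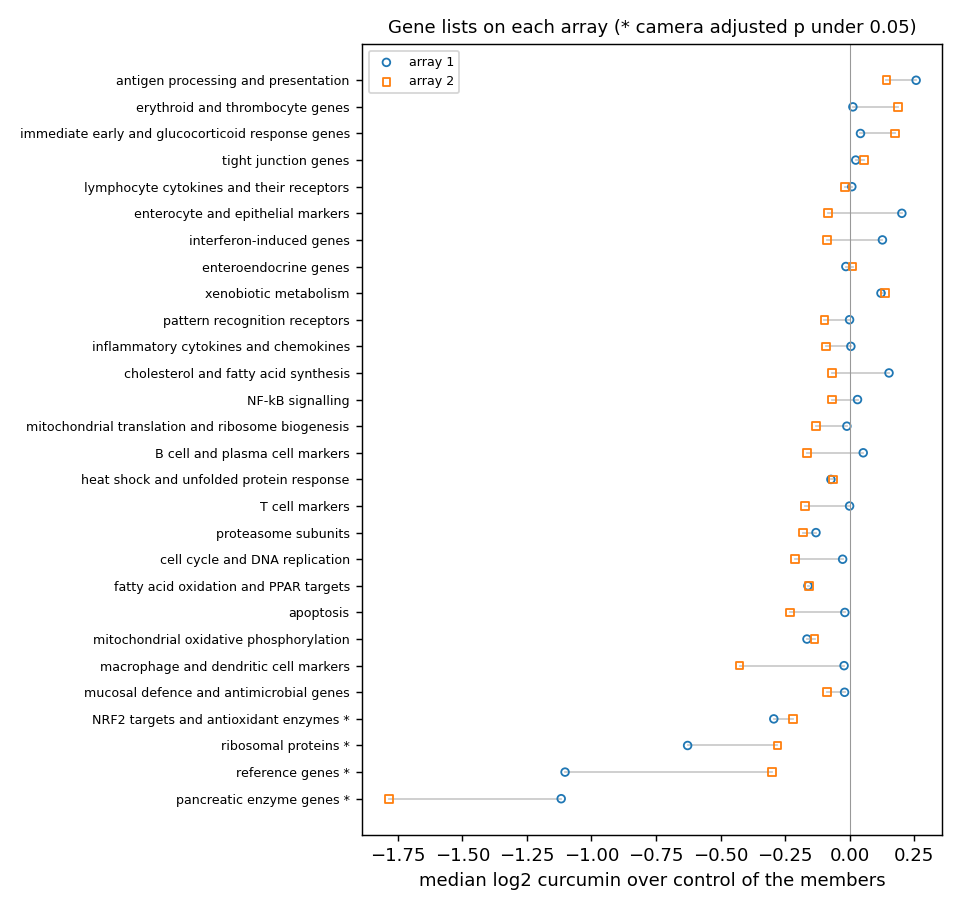
Median log2 ratio of curcumin over control of the members of each of the 28 gene lists on array 1 (circles) and array 2 (squares), in log2 units. Asterisks mark the 4 lists past camera, and pancreatic enzyme genes lie lowest on array 2, at -1.78.

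No list of immune cell or cytokine genes passed camera. Several immune medians lay nearer 0 on array 1 than on array 2. They were -0.00064 and -0.17 for T cell markers, -0.022 and -0.43 for macrophage and dendritic cell markers, and -0.00069 and -0.098 for pattern recognition receptors. Interferon-induced genes went the other way, with 0.13 and -0.088. Macrophage and dendritic cell markers lay at percentile 1.42 of random lists, outside their central 95%. T cell markers had a median log2 ratio of -0.09 with 3 of 11 members higher and 5 lower on both arrays (adjusted p = 0.964), with CD247 at 0.51 ± 0.67 and GATA3 at 0.45 ± 0.24. Medians were -0.08 for B cell and plasma cell markers (adjusted p = 0.750), 0.03 for lymphocyte cytokines and their receptors (0.947), -0.04 for inflammatory cytokines and chemokines (0.857), -0.07 for NF-kB signalling (0.947), 0.01 for interferon-induced genes (0.704), -0.03 for pattern recognition receptors (0.852) and -0.19 for macrophage and dendritic cell markers (0.462). IRF4 had a mean log2 ratio of -0.23 ± 0.12, CD79B 0.14 ± 0.20, IL12RB2 -0.29 ± 0.25, IL10RB -0.26 ± 0.29, AREG 0.54 ± 0.18 and CCL1 0.31 ± 0.24. TNFRSF1A stood at -0.27 ± 0.37, OASL at 0.93 ± 0.31, IFI35 at -0.71 ± 0.88, IFIH1 at 0.47 ± 0.48 (other probes 0.21 and -0.085), CTSB at 0.63 ± 0.83 and LY86 at -0.49 ± 0.41. MARCO was not well above background in the curcumin channels. Its bound equalled its measured mean log2 ratio of -0.09 ± 0.12 and so bounds nothing. The ratio was -0.0091 on array 1 and -0.18 on array 2. With Agilent's processed signals LY86 stood at -1.95, IL10RB at -1.22, IFIH1 at 1.35 and IL12RB2 at -0.87. TNFRSF1A at -0.08 and CCL1 at 0.20 were smaller in size there. Medians there were -0.71 for the macrophage and dendritic cell list, -0.31 for NF-kB signalling and -0.30 for B cell and plasma cell markers. A p that misses the threshold does not show that these genes were unaltered.

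Antigen processing and presentation genes had a median of 0.16 (adjusted p = 0.119), with PDIA3 at 1.07 ± 0.27 and LGMN at -0.97 ± 0.57, and immediate early and glucocorticoid response genes one of 0.07 (0.225), with KLF6 at 0.93 ± 0.25. Erythroid and thrombocyte genes, markers of blood cells, had a median of 0.10 (0.0510), and their haemoglobin gene HBBA, named HBD on the array, stood at 1.17 ± 0.10, a second haemoglobin beside HBA1. Markers of the gut lining gave 0.02 for enterocyte and epithelial markers (0.704), with EPCAM at -1.07 ± 1.37 and KRT40, matched as a synonym of KRT20, at -0.84 ± 0.52, and 0.06 for tight junction genes (0.750), with CLDN10 at -1.10 ± 0.42 and MPP5 at 1.05 ± 0.088, whose other probe stood at 0.017. Mucosal defence and antimicrobial genes gave -0.23 (0.714), with FCGBP at 1.19 ± 0.28 and PIGR at -0.71 ± 0.90. Without the bright-background spots EPCAM stood at -0.46, KRT40 at -0.31 and PIGR at -0.25, and with median centring these were 0.41, 0.56 and 0.61. Enteroendocrine genes gave -0.0011 (0.750), with CCK at 0.85 ± 0.36 and CHGA at -0.34 ± 0.24.

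The remaining metabolic and cell maintenance lists did not pass camera in this setting. Medians were -0.18 for mitochondrial oxidative phosphorylation (adjusted p = 0.0510), -0.15 for apoptosis (0.0510), -0.12 for cell cycle and DNA replication (0.0510), -0.12 for proteasome subunits (0.0510), -0.14 for fatty acid oxidation and PPAR targets (0.0829), -0.08 for mitochondrial translation and ribosome biogenesis (0.325), -0.09 for heat shock and unfolded protein response (0.668), -0.0047 for xenobiotic metabolism (0.509) and -0.06 for cholesterol and fatty acid synthesis (0.704). Of the 44 cell cycle genes, 32 were lower and 4 higher on both arrays, with STMN1 at -0.62 ± 0.52 and MELK at 0.64 ± 0.15. Of 13 alternatives, processed signals and the series value table held the same ratios. The cell cycle list passed in 9 of the 13, both of these included, with adjusted p from 2.85e-05 to 0.115. Its medians there ran from -0.80 with processed signals to -0.08 with median centring. It did not pass with an estimated correlation (adjusted p = 0.892) or in fry (adjusted p = 0.599). Mitochondrial oxidative phosphorylation passed as lower in 3 of 13 and enterocyte and epithelial markers as higher in 2 of 13. Antigen processing and xenobiotic metabolism passed as higher with median centring alone. Apoptosis and proteasome lists as lower, and erythroid genes as higher, passed with the mean of a gene's probes alone. With an estimated correlation, a test on 1 residual degree of freedom, each of these had an adjusted p = 0.892. Other values were NDUFA10 at -1.50 ± 1.20, NDUFA9 at -1.22 ± 1.05, DAP at 0.98 ± 0.11, CASP1 at -0.87 ± 1.06, PSMA4 at 1.00 ± 0.11 and PSMC6 at -0.70 ± 0.79. The other probe of PSMA4 stood at -0.23. PLIN2 had 1.15 ± 0.79, ACADL -0.86 ± 0.39, MRPS31 -0.96 ± 0.60, MRPL48 -0.93 ± 0.73, HSPA2 0.70 ± 0.64, CYP3A5 -1.21 ± 1.21 and INSIG1 1.00 ± 0.36. Adjusted over the list alone, xenobiotic metabolism had 5 members higher, cholesterol and fatty acid synthesis 3 and erythroid genes 2. Tight junction genes had 2 higher and 2 lower. Apoptosis, proteasome, antigen processing and mucosal defence had 1 higher each, and the other lists outside the 4 had 0. Over all genes tested each had 0. Median and mean differed in sign for T cell, pattern recognition and epithelial markers, both cytokine lists, xenobiotic metabolism, cholesterol synthesis and enteroendocrine genes.

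Across the 17766 probes, the log2 ratios of the 2 arrays correlated with a Pearson r of 0.422 and a Spearman rho of 0.485 once turned to curcumin over control. Before turning, r was -0.422. Probes are not independent replicates, so no p is given. The same direction held for 69.0% of probes and 66.9% of named genes, and for 6.55% of named genes with median centring. Without outlier-marked spots in the normexp fit and the test r was 0.683, without the bright-background spots 0.669, and with median centring in place of loess it was -0.492.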

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

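The fits without outlier-marked spots, without the spots of bright local background and without background-outlier probes, and the list matching with 10 matches left out, were chosen after seeing the data. The first leaves outlier-marked spots out of both the normexp fit and the test (16296 probes, 5218 genes), so its differences belong to no single choice. Among the 28 lists, 11 kept their direction in camera in every alternative run and 17 did not. By the sign of the median, 7 did and 21 did not. By log2 ratio, among 71 named genes 50 did and 21 did not. Pancreatic enzyme genes kept both direction and threshold in 13 of 13 such settings, apart from the estimated correlation and fry. Processed signals and the series value table, both among the 13, held the same ratios. The estimated correlation, on 1 residual degree of freedom, could hardly have passed any list. Signal over background limits the data: the median probe lay 20.3 intensity units above background in Cy5 and 16.7 in Cy3 on array 1. The separate-channel fit with treatment and dye as terms could not be fitted, since with both terms the log ratios of 2 arrays keep no residual degree of freedom and the intraspot correlation came out at 1, which lmscFit does not accept. Each log ratio compares the RNAs of 1 array, so the pairing by array is part of every fit. The trend and robust eBayes does not enter camera, so it gives no list values. Where a cause is not named, the cause was not tested.

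Genes changed between the diets numbered 0 as reported, 125 (103 higher, 22 lower; 400 probes) with trend and robust eBayes, 2 (both lower, AMY2A and PNLIPRP1) with the mean of a gene's probes, 9 (4 higher, 5 lower; 18 probes) without outlier-marked spots and 15 (6 higher, 9 lower; 48 probes) without bright-background spots. With the mean of a gene's probes, eBayes and the adjustment ran over genes rather than probes. AMY2A and PNLIPRP1 had 1 tested probe each, so their ratios did not change there. Genes at least 2-fold apart on both arrays numbered 50 (40 higher, 10 lower) as reported. They were 443 (243 higher, 200 lower) with Agilent's processed signals and with the series value table alike, 6 (6 higher, 0 lower) with median centring, 0 (0 and 0) with scaling between arrays, 219 (156 and 63) at a threshold of 1.5, 104 (83 and 21) without outlier-marked spots and 96 (74 and 22) without bright-background spots. Without background subtraction 16 were lower. On a single array the count ranged from 153 to 366, with 124 to 165 higher and 29 to 201 lower.

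Lists past the test numbered 4 as reported, 2 without background subtraction, with processed signals, with scaling, with the series table and without bright-background spots (in each of these, the pancreatic and cell cycle lists), 9 with the mean of probes, 0 with an estimated correlation and 0 in fry, and 7 lay outside the central 95% of random lists. Those 7 were the pancreatic, NRF2 and reference lists, cell cycle (percentile 0.23), apoptosis (2.29), macrophage and dendritic cell markers (1.42) and immediate early genes (97.6). Ribosomal proteins lay inside, at percentile 10.74. The correlation of the arrays was 0.422 as reported, 0.665 without background subtraction, 0.679 with processed signals and with the series table, 0.683 without outlier-marked spots and 0.669 without bright-background spots, and reversed with median centring to -0.492 (Spearman -0.593).

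Median centring turned more values than any other alternative, and the named genes that turned did so there. List medians became 0.48 for NRF2 targets, 0.75 for ribosomal proteins, 0.38 for reference genes, 0.39 for oxidative phosphorylation, 0.66 for proteasome subunits, 0.58 for fatty acid oxidation, 0.56 for mitochondrial translation, 0.56 for heat shock, 0.26 for mucosal defence, 0.045 for pattern recognition, 0.15 for inflammatory cytokines, 0.51 for NF-kB signalling and 0.18 for T cell markers. With the camera direction kept, medians also changed sign for apoptosis (0.23), B cell markers (0.22), cholesterol synthesis (0.74), xenobiotic metabolism (0.41) and enteroendocrine genes (0.34). Log2 ratios became 0.41 for PRDX1, 0.50 for MT4, 0.26 for GSTK1, 0.0073 for RPL4, 0.35 for RPS23, 0.024 for PGK2, 0.43 for CASP1, 0.094 for STMN1, 0.41 for PSMC6, 0.58 for ACADL, 0.16 for LGMN, 0.027 for MRPS31, 0.057 for MRPL48, 0.067 for CYP3A5, 0.43 for IFI35, 0.41 for EPCAM, 0.56 for KRT40, 0.61 for PIGR, 0.27 for IRF4, 0.57 for CHGA and 0.78 for TNFRSF1A. The size of a named gene's log2 ratio moved by over 1.5 times, with its sign kept, in other settings too. Without outlier-marked spots 9 of 59 became larger and 7 smaller, without bright-background spots 7 of 71 and 12, and with processed signals 15 of 71 and 13. MARCO, not well above background with curcumin, had -0.09 as reported and -1.84 with processed signals, and ACADL -0.86 and, without bright-background spots, -0.28. The median log2 ratio of all named genes was 0.33 with median centring and -0.03 as reported. Turned values such as 0.0073 for RPL4 and 0.024 for PGK2 thus stayed under the median gene, while others such as 0.78 for TNFRSF1A lay above it. With median centring only 6.55% of named genes had the same direction on both arrays, so for most genes Cy5 over Cy3 kept its direction through the dye exchange.

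Elsewhere the camera or fry direction turned for uncalled or lost lists, with these medians. Ribosomal proteins, inflammatory cytokines and T cell markers had -0.091, -0.055 and -0.18 without background subtraction, -0.13, -0.26 and -0.43 with processed signals and with the series table, 0.011, -0.070 and -0.22 without outlier-marked spots, and -0.070, -0.072 and -0.21 without bright-background spots. T cell markers also had -0.018 without a filter on dim probes, -0.14 with a stricter one, -0.10 without background-outlier probes, -0.013 with scaling and -0.093 in fry. Scaling turned B cell markers (0.065), enteroendocrine genes (-0.041), lymphocyte cytokines (0.023) and NF-kB signalling (0.014). Offset 10 turned epithelial markers (0.045), and no filter turned pattern recognition (-0.00032).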

Other observations

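The tests of dye bias and of the bright-background spots were chosen only after the results, or a near equivalent of them, were seen. Those of pancreatic RNA and of sex were written before their values were seen.

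Pancreatic enzyme genes had lower values with curcumin. A gene-specific dye bias would have given opposite signs on the dye-swapped arrays, but 10 of the 12 members had the same sign on both. More pancreatic tissue RNA in the control samples is a candidate source, and the 8 tested pancreas genes outside the list had a median log2 ratio of -0.091, which meets the bound written against it. That bound took no account of brightness, and a condition on it was added only after this value was seen, because the genes had a median log2 intensity of 7.90 against 9.06 for all named genes and 10.1 for the enzyme genes. This median comes from the reported fit alone. GCG is also a member of the enteroendocrine list, so it does not mark pancreas alone. All 8 were negative on array 2, from -0.83 for INS to -0.069 for GCG. On array 1 IAPP and NR5A2 were positive and the others ran from -0.079 to -0.015. Dim genes cannot show a small share of foreign RNA. The only brighter one, IAPP, had 0.33 on array 1 and -0.38 on array 2. This source therefore stays open, as does an untested effect of the diet.

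Counts of changed genes depended on which spots entered the normexp fit. A few spots of bright local background may distort the fit of array 1. Without them the Cy3 background mean moved from -338 to -9.15, as that explanation requires.

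A different share of female birds in the RNA pools could have added sex-linked differences. The 36 tested probes on chromosome W, which hens alone carry, had a median log2 ratio of -0.0027, with 0.01 on array 1 and 0.02 on array 2. These values lay inside the bound written against a difference in sex. Only the reported fit was used, and simulated log2 ratios of 1 came out at 0.72 even with array 2 backgrounds on both arrays. Whether these probes measure transcripts of hens alone was not tested. The 378 probes on chromosome Z had a median of 0.01.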
